A study of Mus musculus with 96 samples.

How the data were processed

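RNA was measured in single mouse embryonic stem cells of the E14 line, in the RNA part of a protocol that separates messenger RNA from DNA of the same cell. Per the labels' protocols, RNA and DNA were parted by G&T-seq and the cDNA was made into libraries with the Nextera XT kit. The series lists 76 wells of cells grown in serum with leukaemia inhibitory factor (serum/LIF), 16 wells of cells grown in 2i medium and 4 wells with no cell. Values were analysed for 61 serum/LIF cells. The 2i wells and the wells with no cell were not analysed here, so no comparison between growth conditions was made.

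The deposited raw table holds counts per gene, as whole numbers, for 36300 rows, of which 95 are ERCC spike-in names. Per the submitters' processing notes, GSNAP, SAMtools 0.1.18, bedtools 2.19.1 and DESeq2 were used with the GRCm38 build. The counting rule, the annotation release and the use of strand are not given in the sources used here, so counts of overlapping genes and of near-identical family members are uncertain. The labels name no molecular identifiers, so reads are not independent molecules, and intervals and limits from counts cover counting error only. Gene symbols were found for 34880 of the 36205 other identifiers. Coordinates are from GENCODE M21 on GRCm38.

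The deposited normalized table holds a signal per gene for 21255 rows, which the authors scaled from the raw counts. Each non-zero value equals the raw count times 1 of 61 factors, and those factors match the inverse of DESeq2 median-of-ratios size factors computed here, with a largest relative gap of 1.91e-06. The factors run down the rows instead of staying with a cell, and 1.65% of non-zero values carry the factor of their own cell, at a relative tolerance of 0.0001. The raw counts were therefore the basis of each result, and the deposited normalized table was used as an alternative only.

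Total counts per cell ranged from 2417702 to 6787261, with a median of 4244480. No pair of cells looked like 1 library deposited more than once: pairwise Pearson correlations of log2 values ranged from 0.369 to 0.613 over pairs of cells. Each sample is 1 cell, and the labels name no separate cultures. P-values therefore measure the spread between cells of 1 culture and say nothing about other cultures.

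Genes with at least 10 counts in at least 10 cells were kept, which left 10868 genes. Library sizes were scaled by TMM in edgeR 4.0.16. Highly variable genes were called with modelGeneCV2 of scran 1.30.0, at a Benjamini-Hochberg adjusted p under 0.05. The naive pluripotency score was the mean z-score of log2(CPM + 1) over 17 measured members of a fixed list, scaled to an SD of 1. Slopes on the score were tested by the edgeR quasi-likelihood test with the share of genes detected as a covariate, over 10851 genes without the list's own members. The SE of an edgeR slope is an approximation, the absolute slope divided by the square root of its quasi-likelihood F. The 23 fixed gene lists were compared with the score by Pearson's r and Spearman's rho with 100000 permutations, two-sided, and with 10000 random lists matched on mean expression. Co-expression was the mean pairwise Spearman rho within a list, with a one-sided p against such random lists. Both used residuals after regression on the share of genes detected, and lists with fewer than 3 measured members were not tested. The gene lists, the designs and most alternatives were chosen before the data were examined.

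The score fell into separate sets of cells, so no correlation over all cells is printed. Correlations are given within the 50 cells below the largest gap and the 11 cells above it, and for all cells only the number of lists or genes past the threshold is given. The sets were not compared with each other.

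The procedures were tested on simulated data, and the simulations without variable genes and the share of calls reached with shuffled scores were added after the first of these tests was seen. The counts of slopes of the same sign within the sets, with their shuffles, and the regression on the mitochondrial share were added after the slopes were seen. For slopes, 35% of 100 genes given a change of 1 log2 unit per SD and 74% of 100 genes given 2 units were called among 10868 genes, with 44 false calls, more than the adjusted threshold allows. For variability, 79% of 200 genes with dispersion multiplied by 4 were called among 10868 genes, with 1702 false calls. Counts were then simulated with no gene above its trend, in 20 runs for each of 2 trends. These runs gave 555 to 1221 calls with the fitted CV2 trend and 1263 to 2050 calls with edgeR's trended dispersion. The adjusted p of modelGeneCV2 was thus not calibrated for these data. For lists, 40 runs of 10 lists with a shared signal recovered 100% of them, and 1.48% of calls against the score and 2.2% of co-expression calls were false. In these runs each gene was shuffled over cells on its own and the score was random, so other relations between genes were absent. The shares of false calls therefore do not hold for real lists, whose genes can vary together for other reasons.

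Named genes followed a rule fixed in advance. It took the 25 variable genes with the largest ratio of CV2 to the trend and the 12 largest slopes in each direction, among called genes with a mean normalized count of at least 50. It added a set of pluripotency and lineage genes, the DNA methylation genes, and up to 4 members of each other list. Ribosomal protein genes, clone names and numbered gene models were counted but not named, and identifiers with no symbol were treated in the same way. Of the genes that this rule takes, 1 is not reported here.

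Alternatives were DESeq2 1.42.0 size factors, scran deconvolution, weaker and stricter filters, thinning to 2417702 counts, other covariates and other scores. The score over 5 genes was set on Nanog, Esrrb, Zfp42, Klf4 and Tbx3, but Tbx3 failed the filter and did not enter it. Cells were also left out, plate rows were fitted separately, and a pseudocount of 10 was used. DESeq2 and limma 3.58.1 were run in place of edgeR, and modelGeneVar in place of modelGeneCV2. Statistics were computed in R 4.3.3 and Python 3.11.15 with scipy 1.17.1.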

Results

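Single E14 mouse embryonic stem cells were profiled by RNA sequencing in a study that links transcriptional to epigenetic differences between cells, and counts were analysed for 61 cells grown in serum/LIF. Total counts per cell ranged from 2417702 to 6787261 (median 4244480), and 5317 to 10032 genes were detected per cell (median 8404). Mitochondrial transcripts took 0.0543% to 4.45% of counts (median 1.97%). With 1 culture and no values for 2i cells, the comparisons below are between cells of 1 condition.

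The first question was which genes differed most from cell to cell. Krt8 and Krt18, keratins of simple epithelia, had ratios of squared coefficient of variation to the trend of 17.5 and 10.7. Zfp42, a marker of naive pluripotency, had a ratio of 12.7 and was detected in 42 of 61 cells. Dnmt3l, a cofactor of de novo DNA methylation, had a ratio of 13.1, with counts in 28 cells. Other genes with high ratios were Klhl13 (14.7), Upp1 (13.6), the extracellular matrix gene Fn1 (13.5), the Nodal antagonist Lefty1 (12.5), the cyclin gene Ccnd2 (11.7), Tagln (11.6), Thbs1 (10.5), Mylpf (10.2), Morc1 (9.18), Gstm1 (9.13), Spp1 (9.10), Krt19 and Ccn1 (8.98). Lgals3 (11.7) and Rnf17 (9.61) lie on chromosome 14, whose summed counts were low in some cells.

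Several ratios rested on 1 cell. The mesendoderm gene Mixl1 had the highest ratio of the named genes, 43.7, and 76.7% of its normalized counts came from the cell in well D07; without that cell its ratio was 13.6. Without its highest cell, Fn1 had a ratio of 7.07 (D07), Dnmt3l 6.74 (E09), Ccnd2 6.86 (G09), Ltbp1 3.84 (G06), Timp3 4.65 (G03), Epha4 4.76 (H10) and Cd44 5.97 (G03). Rasgrp2, at 10.3 with all cells and 2.63 without B10, and Gstm1, at 3.25 without G09, then lay below 3.38, the smallest ratio among the genes past the threshold.

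In all, 571 of 10868 genes passed the threshold in modelGeneCV2, and 213 of them had a ratio below 3.38 without their own highest cell. The count of 571 cannot be read as an excess of variable genes, because counts simulated with no gene above its trend gave 555 to 2050 calls. The highest ratio among well-expressed genes in the simulations was 8.50 with one trend, which 30 measured genes exceeded, and 15.8 with the other, which 2 genes exceeded. Of 17 measured naive pluripotency genes, 10 were among the 571, including Esrrb (4.04), Dppa3 (6.87) and Nanog (3.94, or 2.91 without the cell in C05), an over-representation with an adjusted p of 4.54e-08 in a one-sided Fisher's exact test. Called members also exceeded the background in the mesendoderm list (5 of 6, adjusted p = 2.49e-05), the formative and primed list (6 of 16, adjusted p = 0.000765) and the fibroblast list (3 of 4, adjusted p = 0.00305). The fibroblast list has 19 members, and those that failed the filter include Col1a1, detected in 7 cells, Thy1 in 5 and Dcn in 3. Its called members were Fn1 (56 cells), Tagln (47) and Vim (44), so this result does not show fibroblasts in the culture. Fisher's exact test takes genes as independent, while members of a list can vary together. Its background was not matched on mean expression, and the calls come from the test that was not calibrated. The p-values for these lists therefore do not measure how unlikely the counts are. Pou5f1, detected in all 61 cells, had a ratio of 1.11, and Sox2 had 1.24.

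**Figure D1:**
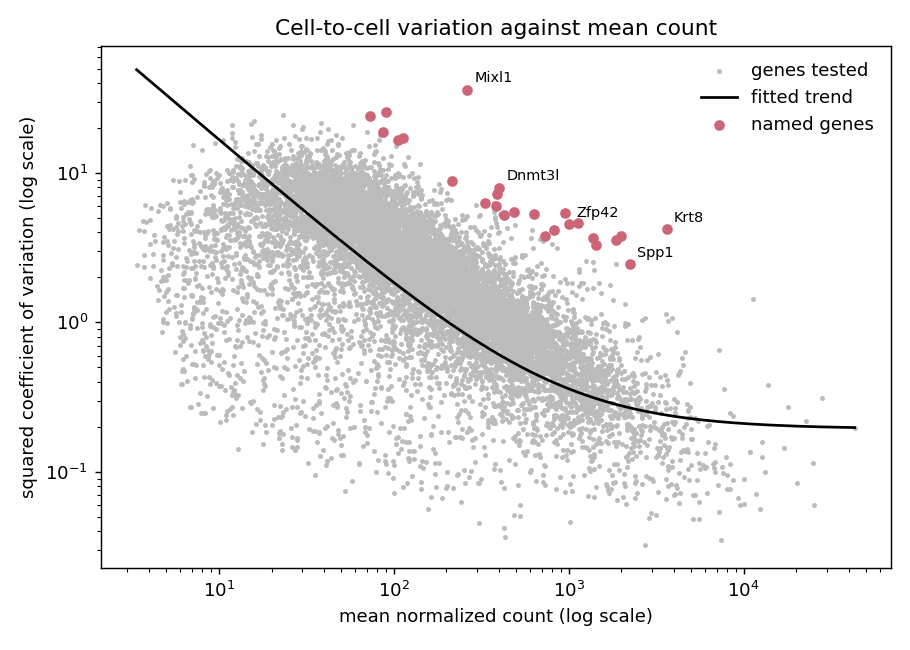
Squared coefficient of variation against mean normalized count, both on log axes, for each of 10868 genes (grey), with the fitted trend (line) and the 25 named genes (red). The named genes lie 8.98 to 43.7 times above the trend, which runs below much of the cloud of genes.

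The second question was how expression followed naive pluripotency, as measured by a score over its marker genes. The naive score ranged from -1.15 to 2.73 SD. The largest gap, from 0.484 to 1.05, parted 50 cells below from 11 cells above. The score was described better by 2 normal components than by 1, by a BIC difference of 43.8. The next largest gap was 0.476, against 0.567, and lay above the cells in F07 and B10. These have the highest mitochondrial share (4.45%) and the fewest genes detected (5317). The place of the split is thus uncertain, and a split above these cells was not tested.

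**Figure D2:**
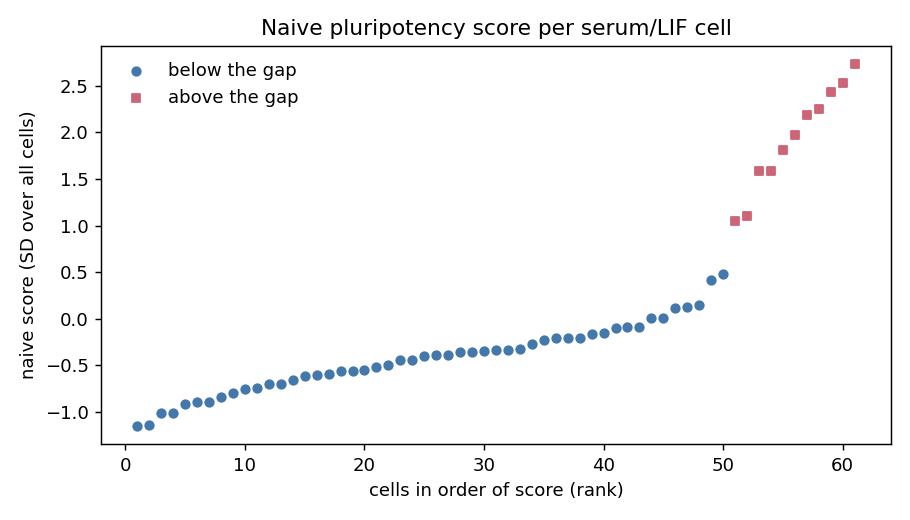
Naive pluripotency score in SD units for each of 61 serum/LIF cells, in order of score. The 50 cells below the gap (circles) reach 0.484 and the 11 cells above it (squares) start at 1.05.

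Across all cells, 494 genes had a slope on the score by the edgeR quasi-likelihood test, of which 85 rose and 409 fell. The count was 252 without the cells in D05 and C07 and 129 with the score over 5 genes, which Tbx3 did not enter because it failed the filter. The rising share was 17.2%, against 30.3% without the filter, 33.3% with the stricter filter, 43.4% with limma-trend and 11.3% with DESeq2. To pass the filter, a gene seen only above the gap needed 10 of 11 cells, and one seen only below it 10 of 50. How far this shaped the shares was not tested. Gbp3 fell by 4.71 ± 0.90 (SE, n = 61 cells) on the log2 scale per SD and Gbp2 fell by 4.60 ± 0.76, both interferon-induced GTPases. Nt5e fell by 4.52 and the scavenger receptor gene Colec12 (chromosome 18, 9707595 to 9882644) fell by 4.46 ± 0.62. Alox15 (-4.40), the antigen-trimming peptidase gene Erap1 (-4.38), the desmosome gene Dsp (-4.35), Efemp1 (-4.28), Ghr (-4.05), Irgm1 (-4.02) and Chst15 (-4.00) fell too. Among the genes that rose were the cell adhesion gene Jam2 (chromosome 16, 84774123 to 84825928) with 4.57 ± 0.72, Spink1 with 3.33, the piRNA pathway gene Tdrd12 with 3.18, the receptor gene Kit with 2.95 and Cpsf4l with 2.93. Ercc4 (2.36), Fbxo15 (2.27), Mreg (2.26), Triml1 (2.24), Platr3, Calcoco2 and Mok (2.13) rose by less. Gbp2 and Gbp3 share sequence with other family members, so their counts are uncertain. The genes named here were detected in 13 (Triml1) to 43 (Colec12) of 61 cells. Gbp3 (28 cells), Nt5e (22), Alox15 (17), Jam2 (17) and Spink1 (18), among others, had a median of 0 CPM. Where most cells are at 0, a slope cannot be read as a graded change from cell to cell.

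Few slopes passed within either set of cells. Within the 50 cells below the gap, 3 genes passed, Spink1 (8.86 ± 1.67 per SD), Hat1 (1.39 ± 0.24) and Cacng7 (8.55 ± 1.60), the last pair named after their values were seen, and 461 had an unadjusted p under 0.05. Within the 11 cells above it, edgeR called 0 genes, with 884 at an unadjusted p under 0.05. With uniform p-values a share of 0.05 of the 10851 tested genes would reach that limit, which is more than 461 and fewer than 884. Of the 494 genes called over all cells, 446 had a slope of the same sign below the gap, 82 of them at an unadjusted p under 0.05, and 392 had one above it, 40 of them at such a p. These cells are part of the fit that chose the genes, so agreement of sign is raised with no relation at all. In 20 shuffles of the score, the 494 genes with the smallest p gave 350 to 399 of the same sign below the gap, 35 to 65 of them at such a p, and 240 to 381 above it, 21 to 73 of them at such a p. The count of 40 above the gap thus lay within the range of the shuffles, and the other counts lay above theirs. In plate rows A to D, 71 genes passed over 33 cells, and in rows E to H edgeR called 0 over 28 cells. There 415 of 7875 tested genes had an unadjusted p under 0.05, close to the share that uniform p-values would give. When the score was shuffled over cells, a mean of 43.5 genes reached the p of the last call, 8.80% of the calls. Among the 220 of these genes that were detected in most cells that share was 1.20%. Of the 409 genes that fell, 33 lie on chromosome 14, more than its share of tested genes (adjusted p = 0.000235, one-sided Fisher's exact test). Summed counts of chromosome 14 were low in 7 cells, and 6 of these lie above the gap. Whether the 33 genes fell through these cells alone was not tested.

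**Figure D3:**
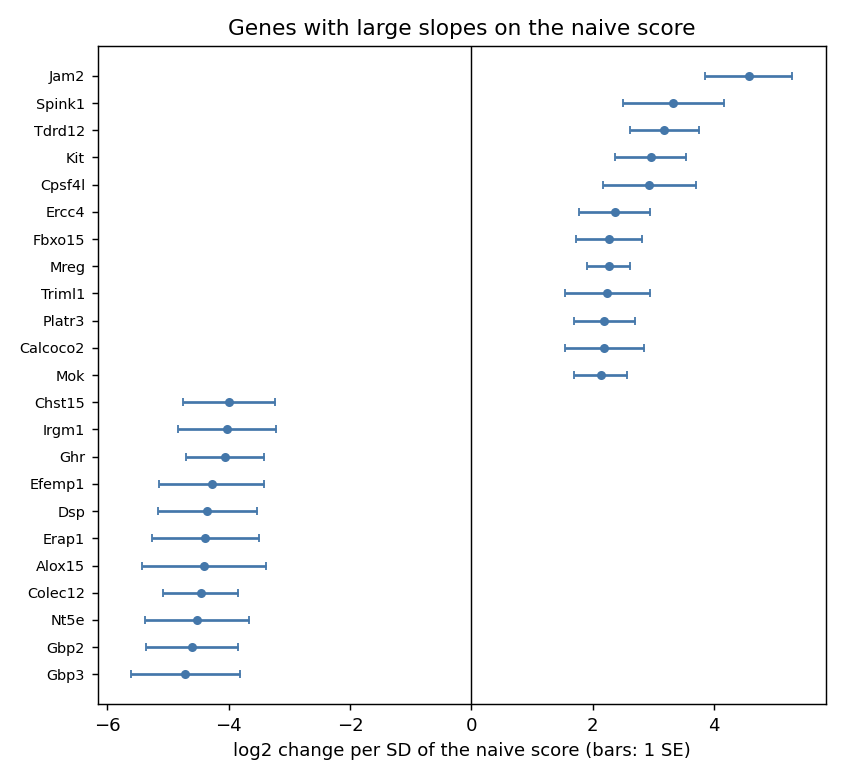
Log2 change per SD of the naive score, with bars of 1 SE, for 12 genes that rose and 11 that fell, the largest slopes reported among called genes with a mean normalized count of at least 50, over 61 cells. Rises span 2.13 (Mok) to 4.57 (Jam2) and falls span -4.71 (Gbp3) to -4.00 (Chst15).

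Mesendoderm genes moved as a group. All 6 measured members fell with the score, also when adjusted over the list alone (6 of 6), with Mixl1 at -3.88 ± 0.95, Cdx2 at -3.56, Fgf8 at -3.34 and the brachyury gene T at -3.19 ± 0.62 (SE). Of 16 formative and primed genes, 5 fell and 11 did not pass, with 7 falling when adjusted over the list alone. Krt18 fell by 3.80, Krt8 fell by 3.71, Sall2 fell by 3.47 and Fgf5 fell by 2.99, whereas Otx2, on chromosome 14, had a slope of -0.54 ± 0.75 (adjusted p = 0.885). Of 22 Polycomb genes, Mtf2 (0.65), Jarid2 (0.69) and Eed (0.41) rose and Yaf2 (-3.47) fell, with 3 rising and 2 falling when adjusted over the list alone. The general pluripotency gene Pou5f1 had a slope of 0.10 ± 0.11 and Sox2 one of 0.71 ± 0.30, neither past the threshold; in that list of 18 genes Rif1 rose by 0.43 and Lefty1 fell by 2.52, with 4 rising and 1 falling when adjusted over the list alone.

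Smaller numbers of genes passed in other lists. The imprinted genes Gnas (-0.77) and Sgce (-3.23) fell among 25 measured. In the list of 9 germline genes silenced by methylation Tex19.1 (1.78) rose, with 1 ribosomal protein gene that is not named by the rule, and Fbxo15 was the 1 gene to rise among 8 LIF and STAT3 targets. Dusp6 (-1.29), a target of ERK signalling, fell among 14, the Wnt target Axin2 (-2.30) among 6, Atf3 (-3.39) and Fos (-1.99) among 11 stress genes, and Cks1b (-0.32) and Lbr (-0.40) among 54 G2/M genes. The mitochondrial gene mt-Nd1 rose by 0.37 among 11. These counts were the same when adjusted over the list alone, except for 1 rising and 3 falling ERK targets and 3 falling Wnt targets. None of 41 S-phase, 19 glycolysis, 29 nuclear oxidative phosphorylation and 14 p53 pathway genes passed in edgeR over all cells, nor when adjusted over the list alone.

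Markers of other cell types were measured in the same cells. Col4a1 (-3.39) fell among 6 primitive endoderm genes, Nes (-2.25) and Hes1 (-2.38) among 5 neurectoderm genes, and Tagln (-2.62) among 4 fibroblast genes, and none of 5 trophectoderm genes passed. The primitive endoderm list has 20 members and the neurectoderm list 15. Those that failed the filter include Gata4, detected in 2 cells, Sox17 in 1 and Sox1 in 0. Measured members include Apoe (61 cells) and Sparc (60), so these slopes do not show cells of such types. Adjusted over the list alone, 3 primitive endoderm genes fell, 2 neurectoderm genes rose and 2 fell, 2 fibroblast genes fell and 1 trophectoderm gene fell. Gata6 was detected in 3 cells, with 81.2% of its raw counts in the cell in D07. Zscan4c and Zscan4f, markers of a state like the 2-cell embryo, were each detected in 2 cells, and Zscan4d in 0; the list of such markers had 1 measured member, which did not pass. These genes belong to a family of near-identical copies. Tbx3 was detected in 13 cells and did not pass the filter.

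The third question was whether fixed lists followed the score within each set of cells. Over all cells 13 of 21 lists passed by Pearson's r and 11 by Spearman's rho. Against random lists matched on mean expression, some of the 13 did not stand far apart. The primitive endoderm list lay at percentile 5.21, fibroblast at 6.6, p53 at 7.51, LIF and STAT3 targets at 96.8 and Polycomb at 97.2. The others of the 13 lay at 2.14 or below or at 97.66 or above. Passing the permutation over cells thus does not by itself set a list apart from other genes. Within the 50 cells below the gap, the mesendoderm list fell with the score (r = -0.518, permutation p = 0.0001, adjusted p = 0.0021; rho = -0.552, permutation p = 1e-05, the smallest the permutations can give, adjusted p = 0.00021), and r was -0.459 without the 2 cells farthest from the median, in wells C04 and F01. These have the most (10032) and the fewest (6456) genes detected below the gap, and F01 is 1 of the cells with low chromosome 14 counts. The germline list passed by r (0.491, adjusted p = 0.00378) but not by rho (0.348, adjusted p = 0.0927), and r was 0.328 without those cells. The p53 list did the same (r = -0.391, adjusted p = 0.0349; rho = -0.390, adjusted p = 0.0528), with r = -0.295 without them. Refitted without C04 and F01, neither list passed (r = 0.309 for the germline list and r = -0.287 for the p53 list, adjusted p = 0.303 for each). The mesendoderm relation did not pass with the score over 5 genes less Tbx3 (r = -0.0624, adjusted p = 0.856) or with Esrrb alone (r = -0.155, adjusted p = 0.762), nor in plate rows E to H (r = -0.368, adjusted p = 0.401) or without the filter (r = -0.347, adjusted p = 0.152). It passed under 10 of the 14 alternatives that could test it, with adjusted p from 0.00084 to 0.856, the germline list under 10 of 14 and the p53 list under 5 of 16, also failing under alternatives that keep those cells, such as thinning (adjusted p = 0.0706). Within the 11 cells above the gap 0 lists passed the permutation test, although 2 did with cell cycle scores as covariates.

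Because the study pairs RNA with DNA methylation, genes that write, read or erase methylation were followed singly. Tet1 rose by 0.94 ± 0.24 per SD (edgeR adjusted p = 0.0103) and was the 1 member of 19 to pass, also when adjusted over the list alone. Dnmt1 had a slope of -0.04 ± 0.26, Dnmt3a one of -0.03 ± 0.38, Dnmt3b one of -0.17 ± 0.26, Dnmt3l one of 0.36 ± 0.52 and Tet2 one of 1.44 ± 0.56, all short of the threshold. By correlation over all cells 3 of 19 genes passed, Tet1, Tet2 and Dnmt3l, so the tests differed on Tet2 (edgeR adjusted p = 0.148) and Dnmt3l (edgeR adjusted p = 0.895). Within the 50 cells below the gap Dnmt3l (r = 0.445, adjusted p = 0.0127) and Hells (r = 0.455, adjusted p = 0.0127) passed by r, but neither did by rho (0.377 and 0.351, both with an adjusted p of 0.122). Without C04 and F01 r was 0.293 for Dnmt3l and 0.438 for Hells, and Dnmt3l did not pass when refitted without them (adjusted p = 0.438). Dnmt3l passed under 10 of 14 alternatives and Hells under 10 of 16. Tet1 (r = 0.222, permutation adjusted p = 0.542) and Tet2 (r = 0.0943, permutation adjusted p = 0.729) did not pass below the gap. Within the 11 cells above the gap 0 genes passed the permutation test, with r = 0.166 for Tet1 and r = -0.391 for Tet2.

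The last question was which groups varied together. Within the 50 cells below the gap, 13 of 22 lists had a higher mean pairwise rho than matched random lists. Mitochondrially encoded genes were the most coherent (0.444, against a median of 0.0103 in random lists), followed by mesendoderm (0.285), G2/M (0.258), general pluripotency (0.178), S-phase (0.157), p53 pathway (0.152) and glycolysis genes (0.126), each with an adjusted p of 0.000314, the smallest reached, from a p at the limit that 10000 random lists allow. The residuals were not adjusted for the mitochondrial share, which ran from 0.0543% to 3.09% in these cells. How far that share alone gave the value of the mitochondrial list was not tested. Over all cells 14 of 22 lists passed, and within the 11 cells above the gap 5 did. The naive list itself did not pass in either set, which were chosen by a limit on the same score: its mean rho was 0.005 in the 50 cells below the gap (adjusted p = 0.639) and 0.0749 in the 11 cells above it (adjusted p = 0.0711).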

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

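Except for the test by thinning, each test in this part was chosen only after the result it bears on was seen. The design has 1 group and names no biological explanation, so the 1 that was tested, loss of a chromosome copy, came from the data.

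Reads on ERCC names lie outside the main measurement: 14 reads in total, in 8 cells and on 2 of 95 names. Of single cells, only that in B03, with 4 reads, was above the limit of 3 counts that a count of 0 allows. They are too few for a spike-in trend.

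The deposited normalized table carries all 61 factors in every column. With factors indexed down the rows the ratio to the raw count was constant, with a largest spread of 1.69e-14 within an index. A correction per gene, such as length or GC content, is argued against by a median coefficient of variation of the ratio across the cells of a gene of 26.6%. Used as deposited it gave 1382 variable genes, against 485 with the same factors assigned by cell, and 451 genes were shared. What step produced this order stays open.

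The 11 cells above the gap in the naive score had 5317 to 9155 genes detected and a mitochondrial share of 1.39% to 4.45%, and the 50 cells below it had 6456 to 10032 genes and 0.0543% to 3.09%. The BIC difference in favour of 2 components fell from 43.8 to 23.7 after regression on the share of genes detected and to 16.7 with the mitochondrial share added, which argues against these trends as the whole cause but leaves open a part, and other measures of library quality were not tested. After thinning of every cell to the same total, 11 of the 11 cells lay above the largest gap again, and 10 of the 11 were among the 11 highest scores after regression on the share of genes detected. They lie in 6 plate rows and 7 plate columns, although rows E to H alone gave 0 genes with a slope. Shuffling the score over cells gave as many genes as the 494 observed in 1 of 100 orders, the real one, and at most 12 in the others, so chance can be excluded as the source of the count but not of each gene in it.

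Summed counts of chromosome 14 were low in 7 cells, with log2 values against the median cell from -1.39 (E01) to -0.34 (F07), and 6 of these cells lie above the gap; values below -0.3 occurred in 6 cells for chromosome X and 4 for chromosome 3, down to -0.43 and -0.39, and chromosome 19 reached -0.72, so the number of cells hardly sets chromosome 14 apart, while its SD of 0.292 over cells was above the next, 0.19. Few detected genes in those libraries were tested through the other chromosomes, and 4.51% of their values in those cells were below -0.3. This cannot decide, because scaling to library size keeps the other chromosomes from falling together. Several of these cells had few genes detected, such as H10 (6430), F01 (6456), E01 (7033) and B05 (7050), although B09 had 8294 and F07 8256. The cell with the fewest genes (B10, 5317) had a chromosome 14 value of -0.02. Few detected genes thus did not always come with a low value. The share of genes detected, which scaling does not change, was lower for chromosome 14 than for other genes in all 7 low cells. It ran from 56.39% against 75.47% (E01) to 83.7% against 86.47% (F07). Cells without a low value include B10 (59.03% against 60.94%) and F06 (77.97% against 74.62%), but also B01 (78.85% against 85.05%). This argues against few detected genes as the whole cause, except in F07, whose difference was smaller than that in B01. A few abundant genes are argued against, as the median over the 7 low cells was -0.75 without the 20 most abundant genes. Loss of 1 of 2 copies in all 7 cells is argued against by 5 cells more than 0.3 away from -1, while a loss in some of them stays open. Within the sets, the chromosome 14 value and the score had r = -0.181 (permutation p = 0.209, rho = -0.0641, p = 0.66) in 50 cells and r = -0.0634 (permutation p = 0.856, rho = -0.0182, p = 0.967) in 11 cells.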

How the results depend on the processing

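The alternatives without the cells in A07 and B10 (lowest mitochondrial share, fewest genes) and with the deposited factors assigned by cell were chosen after the data were seen; without A07 and B10 there were 581 variable genes, 440 genes with a slope and 14 lists past the threshold. Thinning used every cell, and a limit of 0.5 times the median total removed no cell and so gave no value. A spike-in trend could not be fitted with 14 ERCC reads. No paired analysis was possible because 1 group has values and the replicate numbers are names given in accession order. Over single genes and lists, 2106 values kept their direction and side of the threshold, 387 no longer passed, 12 newly passed and 29 changed sign. Of the slopes, 205 no longer passed; of the counts, 106 stayed within 1.5 times and 31 did not. The cause was not tested, except that sets of plate rows and stricter filters hold fewer cells or genes.

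Variable genes numbered 1472 with no filter beyond 1 count in 2 cells, 214 with modelGeneVar and 1382 with the deposited normalized table, against 571. Genes with a slope numbered 3018 with no such filter and 75 with a filter of 10 counts in 0.5 of the cells, against 494. Without the 2 cells farthest from the median of the score (D05 and C07) they numbered 252. The score over 5 genes, less Tbx3, gave 129, plate rows A to D gave 71 and the DESeq2 Wald test gave 961. In rows E to H edgeR called 0 genes, with 415 of 7875 at an unadjusted p under 0.05. With limma-trend 265 genes rose and 345 fell, a rising share of 43.4% against 17.2%; 454 of the 494 genes were shared with DESeq2 and 230 with limma-trend.

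Lists past the threshold over all cells numbered 8 with the stricter filter, 3 in rows A to D and 1 in rows E to H, against 13. Below the gap they numbered 1 with no filter beyond 1 count in 2 cells and 1 without the 2 farthest cells of that set (C04 and F01), and 0 with the stricter filter, with the score over 5 genes, with Esrrb alone, in rows A to D and in rows E to H, against 3. Above the gap 2 lists passed with S and G2/M scores as covariates, against 0. DNA methylation genes past the threshold over all cells numbered 1 with the stricter filter, 5 without the 2 farthest cells and 0 in rows E to H, against 3. Below the gap they numbered 1 without C04 and F01 and 1 in rows A to D, and 0 with the stricter filter, with the score over 5 genes, with Esrrb alone, in rows E to H and with a pseudocount of 10, against 2. These counts of 0 are from permutation tests. Fewer lists could be tested with the stricter filter (17, without mesendoderm and germline), in rows A to D (20, without mesendoderm) and in rows E to H (18, without germline) than the 21 of the main settings. Of 19 DNA methylation genes, 12 were tested with the stricter filter (without Dnmt3l and Tet2). In rows A to D 17 were tested, and in rows E to H 14 (without Dnmt3l). These counts do not show that calls left untested in a setting were lost. Other calls were tested and did not pass, such as Tet1 and Tet2 over all cells in rows E to H. Below the gap, Hells and the p53 list were tested in each of these settings and passed in none.

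The slopes that changed sign were all short of the threshold with the main settings. In plate rows E to H the slope of Pou5f1 was -0.12, of Dnmt1 0.13, of Uhrf1 -0.016, of Gadd45b 0.17 and of Zbtb38 1.65. In rows A to D that of Tdg was 0.033 and of Gadd45a -0.12. Dnmt1 had a slope of 0.024 with no filter beyond 1 count in 2 cells and 0.025 without the 2 farthest cells, where Mbd2 had 0.12. With limma-trend the slope of Dnmt1 was 0.16, of Dnmt3b 0.098, of Tdg 0.13 and of Kdm1b 0.15. With plate row as a factor the slope of Dnmt3a was 0.0595, of Uhrf1 -0.051, of Mbd2 1.08, of Zbtb38 0.15 and of Kdm1b 0.14. With plate column as a factor that of Tdg was 0.062, of Mbd1 -0.083 and of Kdm1b 0.32. With S and G2/M scores as covariates that of Dnmt3a was 0.17, of Uhrf1 -0.024 and of Kdm1b 0.077. With no covariate that of Uhrf1 was -0.069, with Esrrb alone that of Dnmt3a was 0.042 and of Tdg 0.041, and with the score over 5 genes the slope of Gadd45a was -0.066.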

Other observations

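Each test in this part was chosen after the values were seen. Meg3 and Rian, maternally expressed RNAs of the imprinted Dlk1-Dio3 region on chromosome 12, were both at 0 in 9 cells, among 14 cells without Meg3 and 10 without Rian. Random pairs of genes matched on mean expression were jointly at 0 in a median of 0 cells, with a 95th percentile of 3. The 9 cells had at least 3384013 counts, so a count of 0 allows at most 0.887 CPM. In the other cells Rian had a median of 183.3 CPM and Meg3 60.1 CPM. Mirg and Rtl1, from the same region, were also at 0 in these 9 cells, but were at 0 in 41 and 40 of all cells. The 9 cells had 5317 to 9291 genes detected, and 4 of them lie above the gap in the naive score.

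The cell in A07 had a mitochondrial share of 0.0543% (95% Wilson interval 0.0518% to 0.0568%), against 0.741% in the next lowest cell, with the second highest number of genes detected, 9881. The Y-linked genes Ddx3y, Eif2s3y and Uty of this male line were jointly at 0 in 2 cells, against a 95th percentile of 1 cell for matched random sets. The cell in D07 held 76.7% of the normalized counts of Mixl1 and 81.2% of the 621 raw counts of Gata6.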
